A study of Homo sapiens with 32 samples.

How the data were processed

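Per the labels' protocols, kidney tissue was frozen in OCT, cross-sections of glomeruli were laser microdissected, and total RNA was made into libraries with the SMARTer Stranded Total RNA-Seq Kit v2 for picogram input and sequenced on an Illumina HiSeq instrument, with the same number of input reads stated for all libraries. The tissue was either a clinical biopsy or a nephrectomy from a deceased donor or from the unaffected part of a tumour kidney. There were 18 diabetic, 9 reference and 5 idiopathic libraries, grouped by the disease named in the labels. The submitters' processing notes name FastQC, STAR 2.4.2b and the hg38 genome. The program that counted reads and the annotation are not given in the sources used here.

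One deposited table of 25522 genes by 32 libraries was used, which the authors quantile normalized, and its unit is signal. All values were multiples of 1/32, all 32 libraries shared the same highest value, and values of 0 had stayed 0, so that each value carries the rank of a gene within its library. The reads behind each value could not be recovered, so that the depth reached is unknown and no counting interval is given. Depth is described by the number of genes above 0 alone. XIST and Y-linked genes (44 in the table) were left out of all tables because the samples are from patients. Symbols are those of the table. GENCODE release 29 gave coordinates for 23059 of them directly, a further 686 were matched through RefSeq synonyms, and 1777 were unmatched. Genes with a further copy, on an alternate sequence or in a pseudoautosomal region, were 1179 in the table and 781 of those tested. Genes encoded by mitochondria were not analysed here.

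Genes were tested if they were above 0 in at least 5 libraries (24239 genes) and their mean lay above the lower 25% of those, which left 18179. The test was limma 3.58.1 in R 4.3.3, with linear models of log2(value + 1), 1 coefficient per group over all 32 libraries, contrasts between groups and empirical Bayes moderation with a trend and robust variances. P-values were two-sided and adjusted with the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison. Camera with an estimated correlation and fry stand beside it. Camera sets a list against the other genes, while fry asks whether its genes move one way on balance and compares it with no other genes. With fry the podocyte, basement membrane and proximal tubule lists passed in diabetic glomeruli (adjusted p = 0.00589, 0.00171 and 0.00171), as did matrix turnover (adjusted p = 0.0285), which camera did not call (median -1.74, adjusted p = 0.226, in alternatives that ran from 0.0285 to 0.954). Among the lists called in the other comparisons, only proximal tubule passed with fry (adjusted p = 0.0384, idiopathic against reference), and complement, which camera did not call, passed there too (adjusted p = 0.0384). The complement list holds C2 and CFB of the major histocompatibility region. In idiopathic libraries 10.4% of the genes of that region were above 0, beside 54.0% of other chromosome 6 genes. With an estimated correlation no list passed in any comparison. Library measures were compared with exact permutation tests in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, adjusted over 6 tests, shares with Fisher's exact test (scipy 1.17.1), and plots were drawn with matplotlib 3.10.9. The class of short and structural RNAs, formed after the data were seen, was taken from gene types and name patterns, without the long host genes of microRNAs. Splits of the libraries were also drawn within the processing set of each disease group, 100 each, for all libraries and for those of the set. Shared calls were simulated with 100 draws of residuals with random signs, the same reference libraries serving both comparisons.

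The groups, tests, gene lists and rule for named genes were fixed before the data were examined. The rule took genes with adjusted p under 0.05, a mean in the upper part of tested genes and at least 80% of the first group's libraries on the same side of the second group's mean, and named the 8 largest rises and the 8 largest falls. Where fewer than 5 passed in a direction, the 5 with the smallest p were named. Up to 4 members with the smallest p were added for each list described, and clone names, pseudogenes and immune receptor segments were not named. Some list members that the rule picks are not reported here. MALAT1 and RPPH1 in diabetic glomeruli and ADIRF fell outside this rule and were added after their values were seen.

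On simulated data with the group sizes used here, 100 genes changed by 4 on the log2 scale were recovered at 68% for diabetic against reference, 24% for idiopathic against reference and 27% for idiopathic against diabetic libraries. Changes of 8 were recovered at 100%, 96% and 98%, and 6, 6 and 8 unchanged genes were called. The changed genes were drawn from those with a mean level above the median. Residuals were shuffled for each gene on its own across all libraries, which removes structure shared by whole libraries, such as background or processing set. These rates therefore need not hold for the data themselves.

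Alternatives fixed at the start were pseudocounts of 0.1 and 10, no filter, a stricter filter (a mean above the lower 50%), re-centring on 13 housekeeping genes, array weights, no trend or robust variances, scores of tubule genes or of immediate early and heat shock genes as covariates, the replicate number as a block, a fit with only the 2 groups compared, list members past the stricter filter alone, and leaving out each library in turn. Chosen after the data were seen were the processing set as a term or a limit, libraries with at least 12000 genes above 0, those of them with under 20% of olfactory receptor genes above 0, the olfactory receptor share as a covariate, a pseudocount of 100, leaving out genes with a further copy, and leaving out diabetic library 5 and idiopathic library 5. A library was placed in processing set 2 when its share of major histocompatibility genes above 0 was under 0.5 times that of other chromosome 6 genes.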

Results

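RNA was measured in glomeruli, the filtering tufts of the kidney, that had been laser microdissected from frozen human tissue. The labels placed 18 libraries in a diabetic nephropathy group and 5 in an idiopathic nodular glomerulosclerosis group, a disease with similar nodules of mesangial matrix, and 9 in a reference group. All disease libraries came from clinical biopsies and all reference libraries from nephrectomies, so that disease and tissue source were inseparable in comparisons with the reference. The labels did not say whether the libraries came from separate persons. P-values here rest on the spread between samples, which moderation drew largely from genes of similar level. A gene's own spread can be wider than its SE implies. Without trend or robust variances, 18 rather than 57 genes passed between diabetic and reference libraries. Limma then called 0 rather than 9 between idiopathic and reference libraries (1474 at an unadjusted p under 0.05), and 99 rather than 98 between the diseases. Values were quantile normalized signal, and changes are differences of mean log2(value + 1) with their standard error (SE). The read depth of each library is unknown from the file, and the number of genes listed above 0 was the only measure of depth.

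The number of genes listed above 0 ran from 4330 to 24412 per library. The mean was 20698 ± 4284 (SD, n = 9) in reference, 14066 ± 5437 (SD, n = 18) in diabetic and 13318 ± 5066 (SD, n = 5) in idiopathic libraries. Diabetic libraries listed fewer genes than reference libraries (two-sided exact permutation p = 0.00449, adjusted p = 0.0135 over 6 tests), and so did idiopathic libraries (exact permutation p = 0.0180, adjusted p = 0.0360). Idiopathic and diabetic libraries did not differ detectably (exact permutation p = 0.785). Olfactory receptor genes, which encode odorant receptors of the nose and serve as a measure of background in kidney, were above 0 for 57.4% ± 41.2 (SD, n = 9) of 372 genes in reference libraries. The share was 19.5% ± 16.96 (SD, n = 18) in diabetic and 9.03% ± 5.58 (SD, n = 5) in idiopathic libraries. It was lower in diabetic than in reference libraries (exact permutation p = 0.00231, adjusted p = 0.0135). The lower share in idiopathic than in reference libraries did not pass after adjustment (exact permutation p = 0.0425, adjusted p = 0.0637), nor did that against diabetic libraries (exact permutation p = 0.194). Among the reference libraries, 3 had this signal at under 5% of the olfactory receptor genes and 6 at 68.8% or more. The 3 listed 14529 to 15850 genes above 0, beside means of 14066 in diabetic and 13318 in idiopathic libraries. The 6 listed 22877 to 24412. The number of genes thus moved with the background, and fewer genes in disease libraries need not mean less depth. Limma called 391 genes between these 2 parts of the reference group, 375 of them lower in the 3 libraries, more than the 57 between diabetic and all reference libraries, and 14 between diabetic libraries and the 3. The labels do not give which reference libraries came from deceased donors and which from tumour kidneys, so that this division cannot be set against the kind of nephrectomy.

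**Figure D1:**
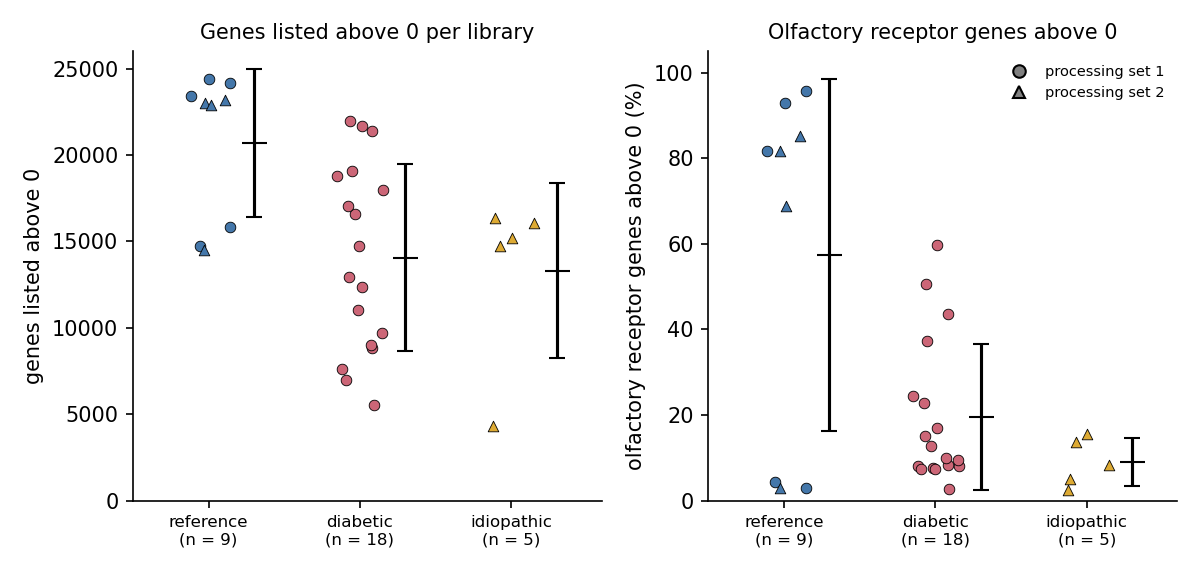
Genes listed above 0 (left, number) and olfactory receptor genes above 0 (right, % of 372) for each library, with the group mean and SD. Reference libraries averaged 20698 genes and 57.4% of olfactory receptor genes, against 14066 genes and 19.5% in diabetic libraries.

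A second division of the libraries became visible in the values. In reference libraries 6 to 9 and the 5 idiopathic libraries, genes of the major histocompatibility region on chromosome 6 were above 0 for 15.7% ± 8.31 (SD, n = 9) of 209 genes, beside 67.5% ± 23.9 of the other chromosome 6 genes. In the 18 diabetic libraries and reference libraries 1 to 5, these shares were 61.3% ± 23.8 (SD, n = 23) and 62.3% ± 23.4. The first 9 libraries are called processing set 2 and the other 23 processing set 1. Each disease group lay within 1 set, and reference libraries lay in both, so that each disease could also be compared with reference libraries of its own set.

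Glomeruli with diabetic nephropathy had lower levels of podocyte genes and of basement membrane genes than reference glomeruli, which addresses what diabetic disease changes in the glomerulus. Both lists passed with camera's preset correlation and neither with an estimated one (each camera adjusted p = 0.158). Nephrin (NPHS1), the main protein of the slit diaphragm between podocyte foot processes, fell by 4.42 (SE 0.99, adjusted p = 0.00641), with all 18 diabetic libraries below the reference mean of 10.83 ± 1.45 (SD, n = 9). Podocalyxin (PODXL), the sialoprotein of the podocyte surface, fell by 3.85 (SE 0.88, adjusted p = 0.00827), and CLIC5, which links it to the cytoskeleton, fell by 4.51 (SE 1.10, adjusted p = 0.0195). COL4A3, a chain of the collagen IV network of the mature glomerular basement membrane, fell by 4.56 (SE 0.91, adjusted p = 7.76e-04), in 18 of 18 libraries. On hg38 with the GENCODE 29 annotation, NPHS1 spans 35825964 to 35869287 on chromosome 19, PODXL 131500262 to 131558217 on chromosome 7 and COL4A3 227164565 to 227314792 on chromosome 2.

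The podocyte list held 20 measured genes, all with a change below 0 and a median change of -2.78. Of these, 3 fell over all genes tested and 13 fell when adjusted over the list alone, and the phospholipase A2 receptor PLA2R1 missed the threshold over all genes (change -3.63, adjusted p = 0.060). The list was lower relative to other genes (camera adjusted p = 3.09e-11), with adjusted p = 0.158 with an estimated correlation, the highest of its 22 alternatives, of which the lowest was 2.81e-20. The mean of its members was 8.86 ± 1.42 (SD, n = 9) in reference and 6.11 ± 1.89 (SD, n = 18) in diabetic libraries. Within processing set 1 the median change was -3.42 (camera adjusted p = 1.20e-16, 18 diabetic and 5 reference libraries). The basement membrane list of 16 collagen IV, laminin and other genes also lay wholly below 0, with a median of -2.05 (camera adjusted p = 3.19e-07, but 0.158 with an estimated correlation, the highest of 22 alternatives, the lowest being 1.18e-12). Only COL4A3 fell over all genes and 9 genes fell when adjusted over the list alone. LAMA5, the laminin alpha chain of the mature membrane, changed by -2.91 (adjusted p = 0.0538), COL4A4, which assembles with COL4A3, by -3.54 (adjusted p = 0.0551) and the linker protein nidogen (NID1) by -3.02 (adjusted p = 0.192), none of which passed. Within processing set 1 the basement membrane list had adjusted p = 8.30e-08 with the preset correlation.

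Markers of the proximal tubule, a cell type outside the glomerulus, moved in the same direction. Of 18 measured markers, none passed over all genes, while 8 fell and 1 rose when adjusted over the list alone, and the median was -2.22 (camera adjusted p = 0.00360, but 0.288 with an estimated correlation, the highest of 22 alternatives, the lowest being 2.37e-04). Examples were the endocytic receptor cubilin (CUBN, -3.52, adjusted p = 0.119), the secreted peroxidase GPX3 (-3.77, adjusted p = 0.122) and the gluconeogenic enzyme PCK1 (-3.76, adjusted p = 0.141). Within processing set 1 the list had adjusted p = 0.00301. No other list of the 26 passed in the test of all libraries, their adjusted p running from 0.0522 for interferon-induced genes to 0.941. Of the interferon list, 3 of 21 genes fell when adjusted over the list alone, and the guanylate-binding protein GBP1 changed by -3.48 (adjusted p = 0.186). This list and the glomerular endothelium list (adjusted p = 0.0782) both passed within processing set 1 (each adjusted p = 0.00409), over alternatives from 0.00312 to 0.954 and from 0.00311 to 0.954. Immediate early genes (median -1.68, adjusted p = 0.426) were lower past the threshold in 3 of 22 alternatives: among libraries with little background (median -2.32, adjusted p = 0.0241), with the processing set as a term (adjusted p = 0.0327) and with the olfactory receptor share as a covariate (adjusted p = 0.0151), over a range to 0.954. Ribosomal protein genes passed in 4 of 22 alternatives (from 1.98e-04 to 0.999) and heat shock genes in 1 (from 0.00123 to 0.954), both as higher, not lower, relative to other genes. The endothelial marker EHD3 changed by -3.58 (adjusted p = 0.0994), and VEGFA, the growth factor that podocytes supply to glomerular endothelium, by -2.13 (adjusted p = 0.132). The immediate early gene DUSP1, a phosphatase of MAP kinases, fell by 4.51 (SE 1.14, adjusted p = 0.0342).

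**Figure D2:**
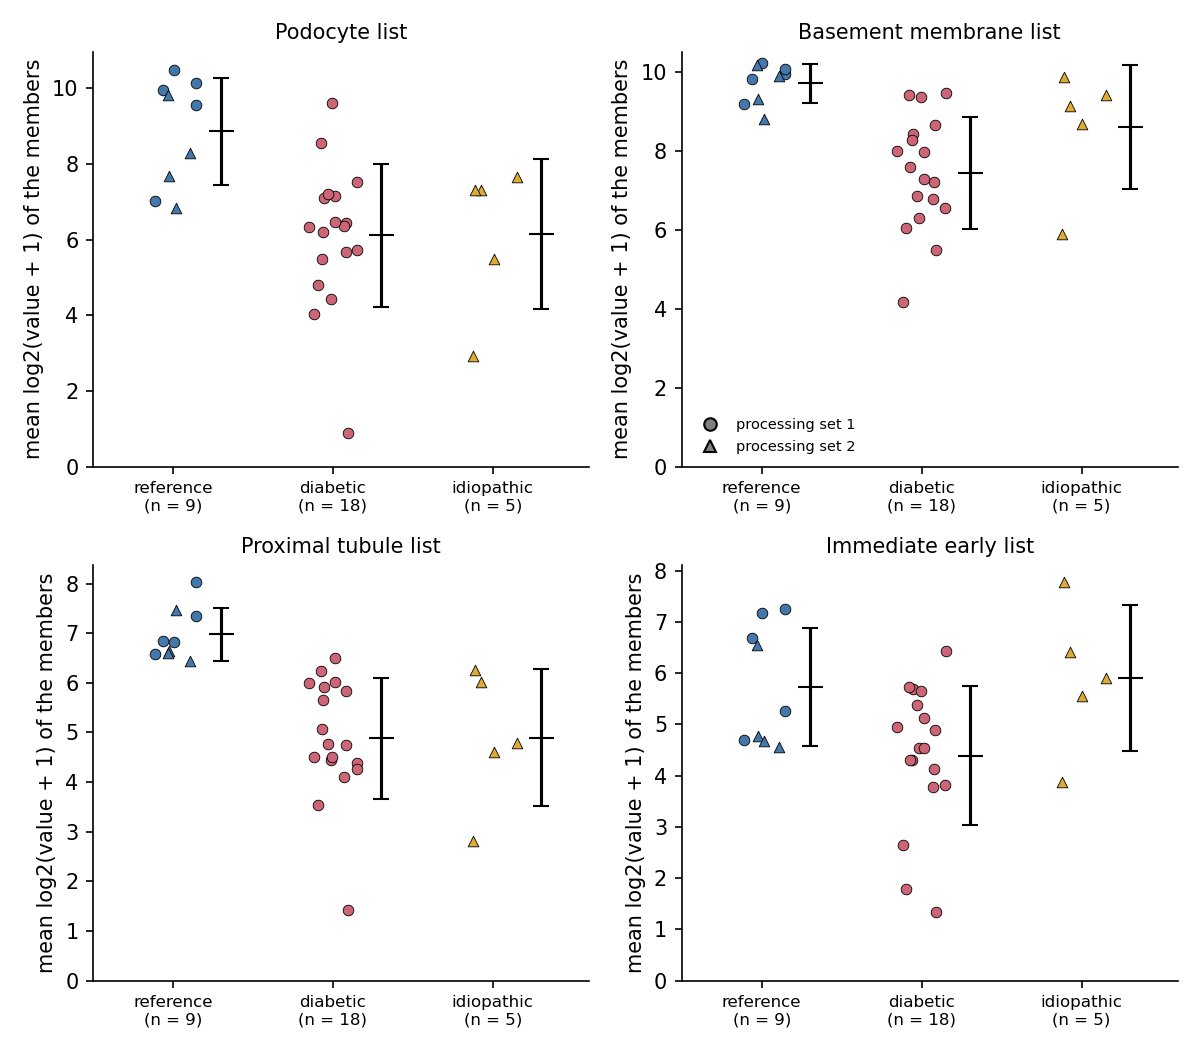
Mean log2(value + 1) of the members of 4 gene lists in each library, with the group mean and SD. The podocyte mean was 8.86 in reference, 6.11 in diabetic and 6.14 in idiopathic libraries, and the basement membrane mean 9.71, 7.44 and 8.60.

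Of 24 genes that rose in diabetic glomeruli, 21 encode short or structural RNAs, a class formed after the calls were seen and not among the fixed lists, with a median change of 4.37. These 21 were selected by their rise, and over all 222 tested members of the class the median was 1.29, with 161 above 0 and 1 that fell past the threshold. The 21 took in a 28S ribosomal RNA gene, which is long, a microRNA gene and a U6 pseudogene, and the other 18 encode RNAs of splicing, of RNA modification and processing and of ribonucleases. The class held 21 of the 24 genes and 1.22% of the 18179 tested (Fisher's exact p = 4.96e-38). Without microRNA genes, ribosomal RNA genes and pseudogenes it held 18 of the 24 and 0.979% of those tested (Fisher's exact p = 3.63e-32). Fisher's test treats genes as independent, which they are not. RNU11, the RNA of the minor spliceosome that recognises its 5' splice sites, rose by 7.62 (SE 0.77, adjusted p = 8.02e-19), from 5.30 ± 3.57 (SD, n = 9) to 12.92 ± 2.04 (SD, n = 18), and all 18 diabetic libraries lay above the reference mean. It lies at 28648600 to 28648733 on chromosome 1. The U1 variants RNVU1-8 and RNVU1-19 rose by 5.35 (SE 1.16) and 5.11 (SE 1.15), and RNU5A-1, an RNA of the major spliceosome, by 5.06 (SE 0.89, adjusted p = 2.54e-05). SNORA61, SNORA54 and SNORA71D, guides of RNA pseudouridylation, rose by 4.995, 4.80 and 4.73, and the microRNA gene MIR4449 by 5.02. Values of RNU11, RNVU1-8, RNVU1-19 and RNU5A-1 are uncertain, since near-identical copies of these genes exist elsewhere in the genome. Within processing set 1, 20 of the 21 kept a rise of at least 0.5 of its size (median 3.02), SNORA54 (1.68) being the exception, but only 5 of the 21 still passed there. The median SE was 1.01 with these 5 reference libraries and 0.92 with all 9, so that the calls ended with smaller changes and a larger SE. Among libraries with at least 12000 genes above 0 and under 20% of olfactory receptor genes above 0 (5 diabetic and 3 reference), the median of the 21 was 0.16. RNU5A-1, SNORA61 and SNORA71D lay on the other side of 0 there, at -0.30, -0.29 and -0.21.

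A pair of abundant nuclear RNAs outside the rule for named genes were chosen after their values were seen. RPPH1, the RNA of ribonuclease P, rose by 4.09 (SE 0.49, adjusted p = 1.44e-11), from 13.03 ± 3.14 (SD, n = 9) to 17.12 ± 1.31 (SD, n = 18). MALAT1, a long RNA of nuclear speckles, fell by 3.70 (SE 0.45, adjusted p = 1.19e-12), from 18.83 ± 0.58 (SD, n = 9) to 15.13 ± 1.61 (SD, n = 18), with 17 of 18 diabetic libraries below the reference mean. MALAT1 held the highest value of the library in 6 of 9 reference libraries and 1 of 18 diabetic libraries, and since all libraries share 1 highest value, the size of its fall is limited by that ceiling. Among the 5 diabetic and 3 reference libraries with little background neither passed: the change of MALAT1 was -2.58 (SE 0.93, adjusted p = 0.610) and that of RPPH1 was 1.28 (adjusted p = 0.661), each the highest of 19 alternatives, the lowest being 2.46e-23 and 1.57e-16. MALAT1 spans 65497688 to 65506516 on chromosome 11 and RPPH1 20343075 to 20343407 on chromosome 14.

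**Figure D3:**
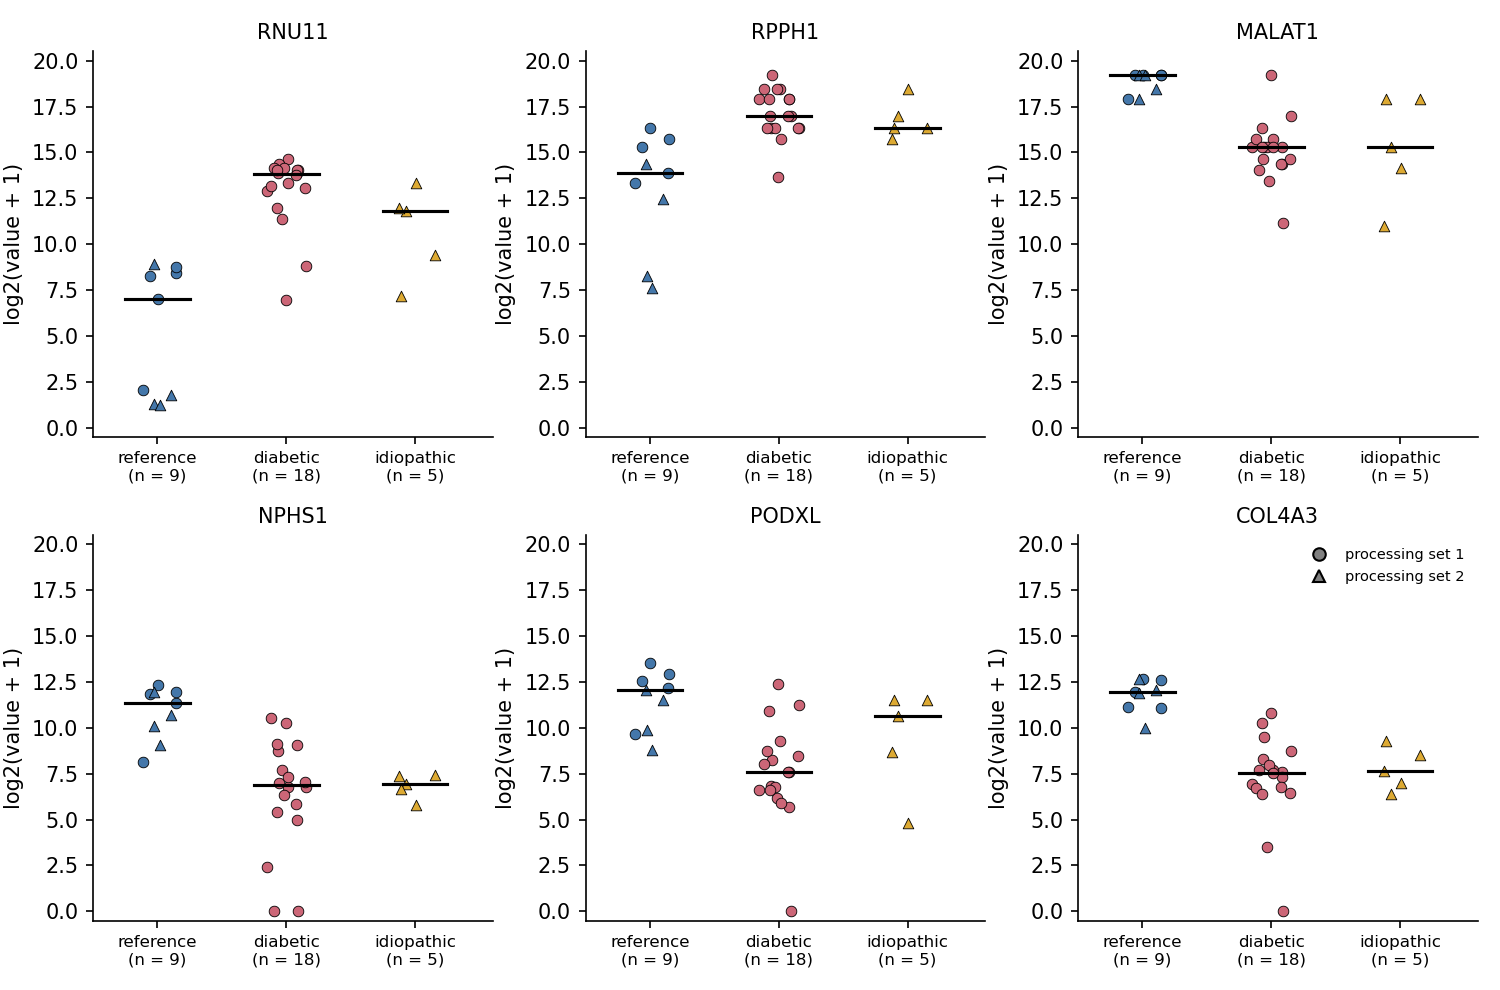
log2(value + 1) of 6 genes in each library, with the group median as a line. MALAT1 fell from a mean of 18.83 in reference to 15.13 in diabetic libraries, RNU11 rose from 5.30 to 12.92, and all 18 diabetic libraries lay below the reference mean of NPHS1.

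The largest falls took in genes of varied function. MIR143HG, the host transcript of a microRNA cluster of smooth muscle, fell by 5.12 (SE 1.19, adjusted p = 0.01002) and was above 0 in 9 of 18 diabetic and 9 of 9 reference libraries. SRGAP2C, a human-specific gene copy whose value is uncertain because its paralogs are near-identical, fell by 4.97, and TRIM5, a factor that restricts retroviruses, by 4.95. ALS2CL, related to the guanine nucleotide exchange factor alsin, fell by 4.81 (SE 0.85, adjusted p = 2.44e-05), in 18 of 18 libraries. WIPF3, TBC1D10A, SYTL4 and TXNDC2 fell by 4.64, 4.63, 4.61 and 4.56 (adjusted p from 0.0342 to 0.0423), and SYTL4 and TXNDC2 were above 0 in 8 of 18 diabetic libraries each.

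Limma called 57 genes of 18179 tested, 24 higher and 33 lower, with 2675 at an unadjusted p under 0.05, and the median change of all genes was -1.003. After libraries were re-centred on housekeeping genes, 35 genes passed, 29 of them higher (82.9% against 42.1%), with a median of -0.37. Within processing set 1, 13 genes passed, 12 of them among the 57, and all 33 lower and 23 of 24 higher genes kept their sign. Among the libraries with little background limma called 0 genes (1370 at an unadjusted p under 0.05), yet the podocyte list was lower there (median -2.81, camera adjusted p = 9.998e-10), with NPHS1 at -4.41 and COL4A3 at -5.02. Without reference library 1, PODXL (adjusted p = 0.0599) and TRIM5 (adjusted p = 0.0524) no longer passed.

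Glomeruli with idiopathic nodular glomerulosclerosis differed from reference glomeruli in 9 genes, a comparison of what this disease changes. RNU11 rose by 5.43 (SE 1.05, adjusted p = 0.00109), from 5.30 ± 3.57 (SD, n = 9) to 10.73 ± 2.43 (SD, n = 5), and RPPH1 by 3.74 (SE 0.68, adjusted p = 4.41e-04). SNORD3A, the U3 RNA of ribosome assembly, rose by 3.57 (SE 0.82, adjusted p = 0.0452) and RMRP, the RNA of a related ribonuclease, by 2.77 (SE 0.65, adjusted p = 0.0461). The further U3 gene SNORD3D did not pass (4.55, adjusted p = 0.0689). All 5 idiopathic libraries lay above the reference mean for these RNAs. Among libraries with little background (4 idiopathic and 3 reference) none of these RNAs passed. RNU11 changed by 1.79 there, RPPH1 by 2.51, SNORD3A by 1.76, RMRP by 1.14 and SNORD3D by 1.58 (limma adjusted p from 0.806 to 0.939). MALAT1 fell by 3.58 (SE 0.61, adjusted p = 8.59e-05), to 15.25 ± 2.87 (SD, n = 5), and ALS2CL by 6.23 (SE 1.16, adjusted p = 4.41e-04). MACF1, a linker of microtubules and actin, fell by 4.42 (SE 1.03), although without idiopathic library 5, which listed the fewest genes, its change was -2.29 (adjusted p = 0.999, in alternatives that ran from 0.00391 to 0.99987). DOCK3, an activator of the GTPase Rac, fell by 5.56 (SE 1.31). Among the libraries with little background none of these falls passed. ALS2CL changed by -5.03 there, MALAT1 by -2.89, DOCK3 by -2.90 and MACF1 by -1.91 (limma adjusted p = 0.162, 0.806, 0.919 and 0.919). BDP1, a subunit of the RNA polymerase III initiation factor, fell by 6.06 (SE 1.41), but within processing set 2 it changed by only -1.22 (adjusted p = 0.860). It has a further copy in the reference sequence and was above 0 in 1 of 5 idiopathic libraries, in 5 of 5 reference libraries of processing set 1 and in 2 of 4 of set 2.

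Podocyte genes were lower as a list in idiopathic glomeruli too. All 20 lay below 0, with a median of -2.63 against -0.99 over all genes (camera adjusted p = 1.19e-06, but 0.762 with an estimated correlation, the highest of 22 alternatives, the lowest being 5.33e-15). None passed over all genes, and 4 fell when adjusted over the list alone. The phospholipase PLCE1, mutated in an inherited nephrotic syndrome, changed by -5.08 (adjusted p = 0.0826), the podocyte phosphatase PTPRO by -4.74 (adjusted p = 0.292), CLIC5 by -4.58 (adjusted p = 0.452) and NPHS1 by -3.99 (adjusted p = 0.480). The mean of the list was 6.14 ± 1.98 (SD, n = 5). Within processing set 2 its adjusted p was 0.0189 (median -1.45). The proximal tubule list was lower (median -2.15, camera adjusted p = 0.0272, but 0.762 with an estimated correlation), with the phosphate transporter SLC34A1 at -4.16 (adjusted p = 0.508) and the dicarboxylate transporter SLC13A3 at -3.82 (adjusted p = 0.553). None of its 18 genes passed over all genes or adjusted over the list alone, and it did not pass within set 2 (adjusted p = 0.120), over alternatives from 0.00552 to 0.762.

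Immediate early genes, induced within minutes by stimuli such as handling, and ribosomal protein genes were higher relative to other genes. Their medians were 0.50 and 0.54, against a median of -0.99 over all genes, and each had camera adjusted p = 0.0222. With an estimated correlation the lists had adjusted p = 0.762 and adjusted p = 1.00, the highest of the alternatives of the ribosomal list being 1.00 and of the immediate early list 0.978, and the lowest 4.76e-06 and 2.35e-04. No member passed over all genes or adjusted over the list alone, and 11 of 21 and 14 of 22 lay above 0. The transcription factors KLF2 and JUN changed by 2.84 (adjusted p = 0.618) and 2.43 (adjusted p = 0.650). Within processing set 2 both passed (adjusted p = 5.27e-04 for ribosomal and 0.00119 for immediate early genes), while among libraries with little background both lay lower than other genes without passing (adjusted p = 0.795 and 0.654). The basement membrane list did not pass (median -1.52, adjusted p = 0.798), and its COL4A3 changed by -4.02 (adjusted p = 0.389).

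Limma called 4 genes higher and 5 lower, with 1489 at an unadjusted p under 0.05. After re-centring on housekeeping genes limma called 0 genes (704 of 18179 at an unadjusted p under 0.05, fewer than unchanged genes would give on average), while RNU11 and the 8 others kept their sign. Within processing set 2 (5 idiopathic and 4 reference libraries) 9 genes passed, of which 1, RNU11, was among the 9 pooled ones. Without idiopathic library 5, ALS2CL (-4.51, adjusted p = 0.112) and RPPH1 (4.002, adjusted p = 0.926) no longer passed, and without idiopathic library 4 neither did RNU11 (4.79, adjusted p = 0.0678).

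Between both diseases, all from biopsies but each in its own processing set, immediate early genes stood higher in idiopathic than in diabetic glomeruli. This comparison addresses how the diseases differ, although disease and processing set coincide in it. Of 21 genes, 17 lay above 0, the median was 2.35 (camera adjusted p = 0.00171, but 0.869 with an estimated correlation), and the list mean was 5.90 ± 1.42 (SD, n = 5) against 4.39 ± 1.36 (SD, n = 18). None passed over all genes, while 4 rose and 1 fell when adjusted over the list alone. The transcription factor EGR1 changed by 4.28 (adjusted p = 0.253), DUSP1 by 4.31 (adjusted p = 0.1995) and KLF2 by 4.27 (adjusted p = 0.240), and IER3, which lies in the major histocompatibility region, was listed at 0 in all 5 idiopathic libraries. Basement membrane genes were higher by a median of 1.22 (camera adjusted p = 0.00439, but 0.869 with an estimated correlation, 14 of 16 above 0), with COL4A1, of the ubiquitous collagen IV network, at 2.49 (adjusted p = 0.566) and the laminin chain LAMC1 at 2.62 (adjusted p = 0.645). Glomerular endothelium genes were higher by a median of 1.19 (camera adjusted p = 0.0366, but 0.992 with an estimated correlation, 15 of 20 above 0), with EHD3 at 3.95 (adjusted p = 0.190) and the guidance receptor ROBO4 at 3.56 (adjusted p = 0.398). TGF-beta response genes were higher by a median of 1.39 (camera adjusted p = 0.0496, but 0.869 with an estimated correlation, 13 of 18 above 0), with TGFB1 at 3.14 (adjusted p = 0.533).

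No member of these 3 lists passed over all genes, and when adjusted over the list alone 1 endothelial gene rose and none of the basement membrane or TGF-beta genes passed. The adjusted p of the 4 lists with an estimated correlation were the highest of their 21 alternatives, and the lowest were, in the order given, 9.45e-07, 0.00104, 5.32e-04 and 0.0137. Without idiopathic library 2 the immediate early and basement membrane lists no longer passed (each adjusted p = 0.0584). The podocyte list did not differ detectably (median -0.08, adjusted p = 0.896), but with the processing set as a term, estimated from the reference libraries, it was higher in idiopathic glomeruli (median 1.20, adjusted p = 0.00670), the lowest of 21 alternatives that reached 0.999. With that term the immediate early list kept its direction (median 2.99, adjusted p = 9.45e-07), as did basement membrane (median 1.28, adjusted p = 0.00146). That term rests on 5 reference libraries of set 1 and 4 of set 2, which also differ among themselves in background. Among libraries with little background only basement membrane passed (median 1.45, adjusted p = 0.0253), while immediate early genes (median 1.82, adjusted p = 0.0835), glomerular endothelium (median 0.42, adjusted p = 0.877) and TGF-beta response (median 0.71, adjusted p = 0.282) did not.

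Only SLC3A1 and ADIRF rose as single genes in idiopathic against diabetic glomeruli. SLC3A1, a subunit of the cystine transporter of the proximal tubule, rose by 5.78 (SE 1.47, adjusted p = 0.0228), with 5 of 5 idiopathic libraries above the diabetic mean, and was above 0 in 5 of 5 idiopathic, 7 of 18 diabetic and 9 of 9 reference libraries. It spans 44275458 to 44321494 on chromosome 2. ADIRF, a gene tied to fat cell differentiation and named after its value was seen, rose by 5.33 (SE 1.46, adjusted p = 0.0459) and was above 0 in 5 of 18 diabetic libraries. PMM2 (5.29, adjusted p = 0.0577), an enzyme of mannose metabolism, SNORD17 (3.44, adjusted p = 0.0832), the retinal reductase DHRS3 (4.90, adjusted p = 0.105) and CITED4 (4.77, adjusted p = 0.127) did not pass. The protease inhibitor TIMP1 changed by 4.52 (adjusted p = 0.170).

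Lower in idiopathic glomeruli were 96 genes, and 91 of them (94.8%) have a further copy on an alternate sequence of the genome or in a pseudoautosomal region, against 4.30% of the tested genes (Fisher's exact p = 1.10e-119). YTHDC1, which binds N6-methyladenosine in nuclear RNA and lies at 68310387 to 68350089 on chromosome 4, fell by 9.77 (SE 1.22, adjusted p = 2.07e-11) and was above 0 in 1 of 5 idiopathic and 18 of 18 diabetic libraries. The histone methyltransferase EHMT2, MLLT6, SNORA54, the GABA receptor GABBR1, the splicing factor PRPF8, the exchange factor ARHGEF10 and the DNA damage mediator MDC1 were listed at 0 in all 5 idiopathic libraries and above 0 in at least 17 of 18 diabetic libraries. Smooth muscle myosin MYH11, of the mesangium and smooth muscle list, fell by 6.81 (SE 1.35, adjusted p = 3.93e-04). It was above 0 in 1 of 5 idiopathic libraries and also has a further copy. The list itself did not pass (median 0.24, camera adjusted p = 0.896).

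Most of these genes were also lower in one part of the reference libraries. In all, 64 genes passed between the 4 libraries of set 2 and the 5 of set 1, all lower in set 2, 62 of them with a further copy and 50 of them among the 96. Of the 96 genes, 94 (97.9%) were lower by at least 2 in reference set 2, with a median of -7.31, while the median of all genes was 0.06. Set 2 was itself defined by few major histocompatibility genes above 0. For genes of that region, such as EHMT2, GABBR1 and MDC1, the lower values in reference set 2 follow from this definition. How many of the 96 and of the 64 lie there was not counted. YTHDC1, on chromosome 4 and thus outside it, was above 0 in 5 of 5 reference libraries of set 1 and 1 of 4 of set 2. With the processing set as a term limma called 0 genes between both diseases (293 of 18179 at an unadjusted p under 0.05, fewer than unchanged genes would give on average). Without the genes that have a further copy it also called 0 (1023 at an unadjusted p under 0.05). Over all genes limma called 98, with 1365 at an unadjusted p under 0.05, and the median change was 0.03.

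**Figure D4:**
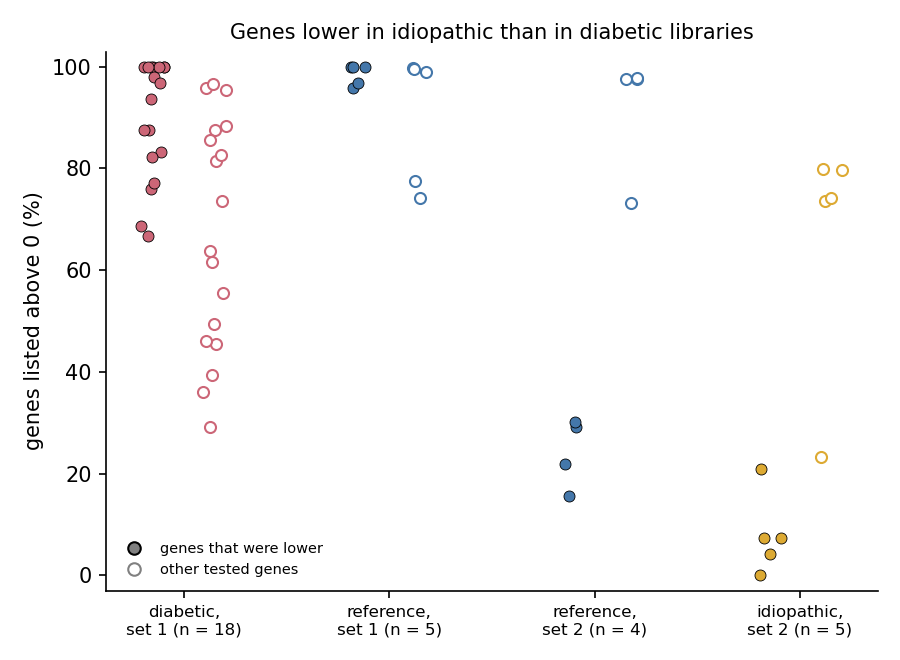
Share (%) of the 96 genes lower in idiopathic than in diabetic libraries (filled) and of the other tested genes (open) that were listed above 0 in each library. The median share of the 96 genes was 95.3% in diabetic, 100% in reference set 1, 25.5% in reference set 2 and 7.29% in idiopathic libraries.

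Changes in both diseases against reference were compared across genes, which are not independent replicates. Pearson's r was 0.329 (bootstrap SD 0.101) and Spearman's rho 0.323 over 18179 genes. Unchanged groups simulated against the same reference libraries gave a mean r of 0.276, from 0.040 to 0.657 in the central 95% of draws, and 63 of 200 draws reached the observed r. The covariance was 0.605 against a simulated 0.345, which 31 of 200 draws reached. When the reference libraries were split so that the comparisons shared none, r averaged 0.116 over 252 splits, from -0.365 to 0.352, and it was 0.142 when each disease was set against its own processing set. The 4 genes that rose in idiopathic glomeruli, RNU11, RPPH1, SNORD3A and RMRP, were all among those that rose in diabetic glomeruli, and ALS2CL and MALAT1 fell in both. Independent lists of these sizes would share 0.00528 and 0.00908 genes, but both comparisons use the same reference libraries. In 100 simulations of unchanged groups against shared reference libraries, none had genes called in both comparisons, so the top genes were taken in the numbers observed. These lists shared a mean of 0.41 higher genes, with 4 or more in 2 of 100, and 0.60 lower genes, with 2 or more in 15 of 100. The random signs break up the division of the reference libraries by background, so these draws cannot show whether that division gave the shared calls. The 4 shared rises are among the 21 short and structural RNAs, which were higher by a median of 4.51 in the 3 low-background reference libraries than in the other 6.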

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

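The tests on genes with a further copy, on the processing sets, on splits within them, on libraries with at least 12000 genes above 0 and on olfactory receptor signal, as a covariate or in the reference libraries, were chosen only after the results they concern or the data were seen.

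Each disease lay in its own processing set, and only the reference libraries span both sets. Between idiopathic and diabetic glomeruli, which is the test of whether the diseases' changes from reference differ, 98 genes differed. Of the named genes these were SLC3A1 (adjusted p = 0.0228), ADIRF (0.0459), YTHDC1 (2.07e-11), EHMT2 (7.49e-07), MLLT6 (6.13e-07), SNORA54 (2.32e-06), GABBR1 (2.69e-06), PRPF8 (2.80e-06), ARHGEF10 (6.32e-06), MDC1 (5.37e-06) and MYH11 (3.93e-04). The lists that differed were immediate early genes (camera adjusted p = 0.00171), basement membrane (0.00439), glomerular endothelium (0.0366) and TGF-beta response (0.0496), none of them with an estimated correlation.

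The genes lower in idiopathic than in diabetic glomeruli mostly share a property of the reference sequence rather than a function. Of them, 94.8% have a further copy (against 4.30% of tested genes), and a candidate explanation is reads lost at such genes in processing set 2, for example where reads that map to more than 1 place were dropped. Against a difference between the diseases as the main source, 97.9% of the genes were lower by at least 2 in reference libraries of set 2 than of set 1. For genes of the major histocompatibility region this follows from how set 2 was defined, and how many of the genes lie there was not counted. Against shallow libraries, 126 genes were lower among libraries with at least 12000 genes above 0. Other splits of the same libraries do not exclude chance: 7 of 100 splits, the real one included, gave at least 98 genes, and the highest other gave 2836, which points to a structure of the samples. With the processing set as a term limma called 0 genes between the diseases (293 at an unadjusted p under 0.05, fewer than unchanged genes would give on average).

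Podocyte genes were lower in diabetic glomeruli. Against background signal, the list had camera adjusted p = 2.27e-10 with the olfactory receptor share as a covariate. Among low-background libraries of both groups its median was -2.81, that of all genes -0.34. Against shallow libraries, it had camera adjusted p = 5.94e-11 among those with at least 12000 genes above 0. That limit kept all 9 reference libraries, so it did not separate depth from background. Both p-values rest on the preset correlation. Alternatives ran from 2.81e-20 to 0.158. The highest, 0.158, came from camera with an estimated correlation (0.39), with which the list did not pass and these checks were not repeated. Tissue source stays open: 0 reference libraries came from biopsies, so that disease and biopsy handling cannot be told apart for these genes. A loss of podocytes or of their transcripts was not tested, and markers of the proximal tubule, another cell type, fell as well (median -2.22).

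Among short and structural RNAs 21 were higher in diabetic glomeruli, with a median of 1.29 over all 222 tested and 1 lower, and MALAT1 was lower. Within processing set 1, 95.2% of these 21 RNAs kept at least 0.5 of their rise. Their mean differed by 3.22 there (SE 0.91), although only 5 of the 21 still passed. The 21 were selected by their rise over libraries that include all of set 1, so that keeping part of it was partly built in. How far the processing set accounts for the rise is therefore left open. Reference libraries with signal at most olfactory receptor genes do not account for MALAT1. MALAT1 changed by -4.07 (SE 0.68) against the reference libraries without that signal, and by -2.58 (SE 0.93) without passing among low-background libraries of both groups. For the 21 RNAs that background cannot be excluded: against the 3 reference libraries without it their median change was 1.63 rather than 4.37, and among low-background libraries of both groups it was 0.16. RNA quality or yield also stays open, since within the 18 diabetic libraries their mean did not follow the genes above 0 detectably (rho = 0.141, bootstrap SD 0.2499, permutation p = 0.574; r = 0.147, permutation p = 0.558, and 0.212 without the 2 farthest libraries). Tissue source is open here as well, and a difference between the diseases and normal glomeruli was not tested apart from it.

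For the count of 57 genes between diabetic and reference glomeruli, chance was made less likely. Of 100 splits 1 reached it, the real one, and the highest other gave 26, or 47 where only libraries of set 1 changed places (again 1 of 100). With 100 splits no smaller share could be reached. For the 13 genes within set 1, 4 of 100 splits reached the count, the real one included, in a test chosen after the data were seen. The highest other split gave 228, which points to a structure of the samples. Chance is thus made less likely for these 13 genes but is not excluded.

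For idiopathic against reference glomeruli, 2 of 100 splits reached the count of 9 genes with the real one, the highest other giving 22, but these splits mix the processing sets, and a split of the same libraries by set gave 163 genes, 162 of them with a further copy. Where only libraries of set 2 changed places, chance was made less likely for this count. Of 100 splits, out of 126 possible, 1 reached it, the real one, and the highest other gave 5. Within set 2 alone the real comparison also gave 9 genes, only 1 of them among the pooled 9, and there chance cannot be excluded, with 9 of 100 splits reaching the count and the highest other giving 423, which points to a structure of the samples. How far the count holds apart from the set is left open.

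A single library lay far from the others of its group in 9 of 101 sets of values tested, all 9 in the idiopathic group and 0 in the reference group. Chance flags about 1 in 20 groups. Idiopathic library 5 listed 4330 genes above 0, the next 14709, and had the lowest TGF-beta response mean, 3.23 against 6.45 for the next. In the same library CLIC5 and PLCE1 were at 0, against 5.34 and 7.23 in the next, and PMM2 was highest at 11.88 against 7.24. BDP1 (4.37) and SLC34A1 (3.46) were above 0 only in idiopathic library 2 of its group, MYH11 (7.96) only in library 1 and YTHDC1 (3.72) only in library 4.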

How the results depend on the processing

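Alternatives with the processing set, the background, depth limits, the 2 shallowest libraries left out, a pseudocount of 100 or genes with a further copy were chosen after the data were seen. The counts of genes that passed depended on most settings, and the cause was not tested except where given. For diabetic against reference (57) they were 24 and 136 with pseudocounts of 0.1 and 10, 149 with 100, 37 without a filter, 35 after housekeeping re-centring, 1482 with array weights, 18 without trend or robust variances, 12 with the tubule score, 7 with the processing set as a term, 13 within the set (fewer libraries), 17 in libraries with at least 12000 genes, 0 in low-background libraries (limma, 1370 at an unadjusted p under 0.05), 20 with the olfactory receptor share, 113 without the 2 shallowest libraries and 87 with only the 2 groups. For idiopathic against reference (9) they were 5 with pseudocounts of 0.1 and of 100, 2 without a filter, 16 with the stricter filter, 2078 with array weights, 2 in libraries with at least 12000 genes, 3 with the olfactory receptor share, 4 without the 2 shallowest libraries and 14 with only the 2 groups. With limma they were 0 after re-centring, without trend or robust variances, with the tubule score and in low-background libraries (704, 1474, 738 and 1001 at an unadjusted p under 0.05, in that order). For idiopathic against diabetic (98) they were 179 with array weights, 183 with the immediate early and heat shock score, 24 in low-background libraries, 7 with a pseudocount of 100, 52 with only the 2 groups, and with limma 0 both with the set as a term and without genes that have a further copy (293 and 1023 at an unadjusted p under 0.05). Of the counts at an unadjusted p under 0.05, 293, 704 and 738 of 18179 are fewer than unchanged genes would give on average. Genes with a further copy have no value where these are left out, and the diseases share no processing set to be compared within.

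Leaving out 1 library at a time gave 31 to 75, 4 to 14 and 58 to 118 genes for these comparisons. The count fell by more than 1.5 times without reference 1 (33), 6 (31) or 7 (31) in the first, without reference 1 (4) or idiopathic 4 (5) or 5 (4) in the second, where it rose without reference 8 (14), and without idiopathic 1 (60), 3 (58), 4 (60) or 5 (63) in the third. The correlation of changes (0.329) was 0.451 and 0.541 with pseudocounts of 10 and 100, 0.501 with array weights, 0.142 with the set as a term or within sets, 0.601 in low-background libraries and 0.589 with the olfactory receptor share.

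Leaving out 1 library also ended calls. Between the diseases these were glomerular endothelium without diabetic 5 or 10 or idiopathic 1, 2 or 3 (adjusted p 0.0603 to 0.3996), TGF-beta response without any 1 of 13 libraries (0.05002 to 0.204), SLC3A1 without idiopathic 1, 3, 4 or 5 (0.0675 to 0.136) and ADIRF (15 libraries). In idiopathic against reference they were proximal tubule without reference 4 or 9 or idiopathic 2, 3 or 4 (0.0537 to 0.176), immediate early without reference 3, 6, 7 or 9 or idiopathic 2 (0.0506 to 0.258), ribosomal genes without reference 3, 6, 7 or 9 or idiopathic 1, 2 or 3 (0.0534 to 0.559), SNORD3A (5 libraries), MACF1 (8), and RMRP, BDP1 and DOCK3 (9 each). In diabetic against reference they were SNORA54 without reference 6, 7, 8 or 9, SRGAP2C without reference 1, 4, 5 or 8, CLIC5 without reference 1, 2, 5, 7 or 8 (0.0532 to 0.0811), DUSP1 (10 libraries), WIPF3 (12), TXNDC2 (14), TBC1D10A (15) and SYTL4 (16).

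The replicate numbers in the labels do not pair the libraries: 19 same-number pairs had a mean correlation of -0.047, 2 of them over 0.1, and 0 of 23 libraries were closest to their own number. With the number as a block the counts were 167, 86 and 254.

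Changed direction: RNU5A-1 (-0.30), SNORA61 (-0.29) and SNORA71D (-0.21) in low-background libraries against reference, and, with the set as a term, YTHDC1 (0.81), MLLT6 (1.496), PRPF8 (0.30), ARHGEF10 (0.26), MDC1 (0.87) and MYH11 (1.56) between the diseases, a term estimated from the reference libraries, of which those of set 2 are lower than those of set 1 at such genes. In idiopathic against reference, the immediate early list (adjusted p = 0.654) and the ribosomal list (0.795) turned lower in low-background libraries, as did the ribosomal list with the olfactory receptor share (0.2997), and heat shock genes were then lower (0.0281), over alternatives from 2.35e-04 to 0.978, 4.76e-06 to 1.00 and 0.0281 to 1.00. The heat shock list holds HSPA1A and HSPA1B of the major histocompatibility region, where idiopathic libraries had few genes above 0. For the 23 named genes called in diabetic glomeruli, 276 of 436 values kept direction and call, 157 lost the call and 3 turned; for the 9 in idiopathic glomeruli 58 of 170 and 112 lost it; for the 11 between the diseases 147 of 189, 36 and 6. The lists called in diabetic glomeruli kept the call in 62 of 66, those in idiopathic glomeruli in 64 of 88 and those between the diseases in 60 of 84. Depth limits all counts: genes at 0 in shallow libraries cannot be told from genes not expressed.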

Other observations

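The tests of short and structural RNAs against olfactory receptor genes were chosen only after the rise of these RNAs was seen.

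Several further lists did not pass with camera in either disease against reference. In diabetic glomeruli the interstitial collagen list changed by a median of -1.07 (camera adjusted p = 0.744), close to the median of all genes of -1.003, complement by -1.28 (adjusted p = 0.941), macrophage markers by -1.40 (adjusted p = 0.688) and targets of the aryl hydrocarbon receptor, which tobacco smoke activates, by -0.58 (adjusted p = 0.758). In idiopathic glomeruli the same lists changed by -0.72 (adjusted p = 0.515), -1.87 (adjusted p = 0.116), -0.34 (adjusted p = 1.00) and -0.95 (adjusted p = 1.00). The complement list of idiopathic glomeruli passed in 2 of 22 alternatives, whose adjusted p ran from 0.0249 to 0.762, and 1 of them was fry. It holds C2 and CFB of the major histocompatibility region, where idiopathic libraries had few genes above 0. Angiogenesis genes changed by -1.27 (adjusted p = 0.744) and -0.63 (adjusted p = 0.981). No gene of these lists passed over all genes in either comparison, and when adjusted over the list alone 1 aryl hydrocarbon receptor gene fell in diabetic and 1 complement gene in idiopathic glomeruli.

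Within the 18 diabetic libraries, the mean of the 21 short and structural RNAs that rose was higher where more olfactory receptor genes were above 0 (rho = 0.486, permutation p = 0.0422, adjusted p = 0.0845 over 4 tests; r = 0.503, permutation p = 0.0329, adjusted p = 0.0845), and r was 0.510 without the 2 farthest libraries, so that the relation did not pass after adjustment. Reference libraries with little olfactory receptor signal had these RNAs higher than the other reference libraries by a median of 4.51, the opposite direction.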
